A study of Mus musculus with 59 samples.

How the data were processed

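RNA of 59 mouse lines was measured on Affymetrix arrays, 1 array per line: 4 ESC clones, 48 iPSC clones, 1 Adeno-iPSC clone and 6 NT-ESC subclones. Per the labels, cells grew in ESC medium with 15% FBS and LIF on irradiated MEFs, were preplated for 45 minutes against MEFs, and total RNA was made into biotinylated cRNA with an Affymetrix kit. The deposited values are log2 intensities of 22626 probe sets, with each array's mean near 0 (medians -0.348 to -0.051). The base of 2, from the range of -4.83 to 6.97, and the centring were inferred from the values, and the method of background correction and summarisation, the scan dates and the batches are not given in the sources used here. No value was missing, no 2 arrays were identical, and values were not quantile normalized. The smallest SD of the difference between 2 arrays was 0.136, and the median within groups 0.225.

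Groups, comparisons, tests, gene lists and 1 set of alternatives were fixed from the labels before the data were examined. Probe sets were named by the gene identifier given for the platform, joined to symbols of assembly GRCm38.p6: 18003 had 1 gene, 287 several and 4336 none. Each of the 11807 genes was represented by its probe set with the highest mean over all arrays. For the 4150 genes with more than 1 probe set, the median lowest correlation between probe sets was 0.357.

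Comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided moderated t or F tests, Benjamini-Hochberg adjustment over all genes, threshold 0.05). All adjusted p-values of single genes in the text are from limma. ESC were compared with the 6 MEF-derived clones and with all 48 iPSC, in fits without covariates. A fit of 42 clones (11 HSC, 11 GMP, 9 granulocyte and 11 fibroblast origin) from 3 animals with cell type and animal as terms gave the test of any difference between cell types, the contrast of 31 blood-derived with 11 fibroblast-derived clones, the contrast of granulocyte with HSC origin, and the test of any difference between animals. PF and TTF labels were counted as 1 fibroblast class, and all TTF clones came from chimera 2. NT-ESC were compared with their donor clones with the donor line as a block, and with ESC. ESC arrays served in 3 comparisons, whose results are therefore not independent.

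Genes named per comparison were drawn from the 12 with the largest difference in each direction among those past the threshold, the 12 widest ranges for F tests, or the 5 smallest p-values where none passed. The Dlk1-Dio3 transcripts, Pou5f1, Sox2, Nanog, Klf4 and Myc could be named in any comparison whatever their p. Not every gene open to naming is printed. From each of 22 gene lists up to 4 members past the threshold are named. The lists cover Dlk1-Dio3 maternal and paternal transcripts, other imprinted, pluripotency, 2-cell-like, epiblast, endoderm, mesoderm, neuroectoderm, trophoblast, germ cell, fibroblast and feeder, haematopoietic, interferon-response and MHC, p53 target, immediate early, glycolysis and hypoxia, cholesterol synthesis, amino acid and ER stress, proliferation, DNA methylation and Polycomb, and sex-linked genes. The 20 lists with at least 3 measured genes were tested in 6 comparisons with camera (preset correlation 0.01, and estimated correlation as alternative), adjusted over all 120 tests. Dcn and Sparc belong to the fibroblast list and to 1 other list each. Clone-to-clone spread was the SD within origin groups pooled over groups, without a test.

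For chromosome parts, 6157 genes with a mean above 0 were ordered along each chromosome of assembly GRCm38.p6 in 235 bins of about 25 genes, and each array's deviation from the other clones of its group was taken as the median per bin. A region was at least 4 bins in a row past 0.2 log2 units, and gene order was shuffled 100 times. Whether the difference between blood and fibroblast origin differed between animals was tested by limma with interaction terms and 99 permutations.

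Alternatives were quantile normalization, leaving out genes under the 40th percentile of mean expression, every probe set on its own, the mean of probe sets, and eBayes with trend and robust settings. Others were 1 fit over all groups, other blocks or none, 1 mean per animal and cell type, and leaving out clones, animals or donor families. For ESC against all iPSC, 1 fit gave each origin group its own term and equal weight. A pseudocount alternative did not apply because the values were already logarithms. Chosen after seeing the data were fits without NT-7, NT-8 and NT-9, without clones with shifted chromosome parts or low Pou5f1, without the MEF-derived clones, and with the fibroblast list mean or the array SD as a covariate. Arrays were regrouped at random 100 times (24 possible ways for NT-ESC and donors) to see how many genes and lists other groupings give, with lists adjusted within each comparison.

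The fits were tested on simulated data in which arrays varied independently of each other. Real clones of an animal or subclones of a donor were correlated. The estimated correlation was 0.250 by animal for ESC against all iPSC and 0.832 by donor for NT-ESC against ESC. The simulation left this out, so the shares recovered may overstate what the fits find in the real data. Of differences of 0.5 log2 units, 43.3% were recovered for ESC against MEF-derived iPSC, 71.6% for ESC against all iPSC, 100% for blood against fibroblast origin and 1.49% for NT-ESC against donors. Of 1 log2 unit the shares were 94.0%, 98.5%, 98.5% and 23.9%. NT-ESC against ESC, with 10 arrays as in ESC against MEF-derived iPSC, recovered 41.8% of 1 log2 unit, so the spread between NT-ESC lines limits the precision as well as the number of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The Adeno-iPSC clone entered only the comparison of NT-ESC with donors.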

Results

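The series holds 59 arrays, 1 per line: 4 embryonic stem cell (ESC) clones, 48 clones of induced pluripotent stem cells (iPSC) from an inducible reprogramming cassette, 1 iPSC clone made with adenovirus (Adeno-2), and 6 ESC subclones from cloned blastocysts (NT-ESC). The iPSC came from MEFs of 1 chimera (6 clones), and from HSCs (11), GMPs (11), granulocytes (9) and cells labelled PF or TTF (11, here 1 fibroblast class) of 3 further animals. Sox2 and Nanog were high in every line, with lowest values of 3.73 for Sox2 (iPSC-34) and 4.18 for Nanog (NT-8), while Pou5f1 was 0.28 in iPSC-32 and 3.78 or more elsewhere. In ESC the group means were 4.84 for Pou5f1, 4.39 for Sox2 and 5.09 for Nanog on a log2 scale centred near 0 per array. Each array correlated at a mean r between 0.982 and 0.993 with the ESC and iPSC arrays, except NT-7, NT-8 and NT-9 (0.889 to 0.940), whose values were also less spread (SD 2.35 to 2.47 against 2.54 to 2.64 in the other 56). On the first principal component of the ESC and iPSC arrays, ESC-2, ESC-3, ESC-4 and the MEF-derived clones lay at one end, fibroblast-derived clones toward the other, and ESC-1 among the clones of other origins. Single-gene p-values below take each clone as 1 unit, since the labels give each array as a separate clone. In fits without origin, animal or donor terms, such as ESC against all iPSC, the spread also holds differences between these. List p-values rest on camera's preset correlation unless an estimated one is named.

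**Figure D1:**
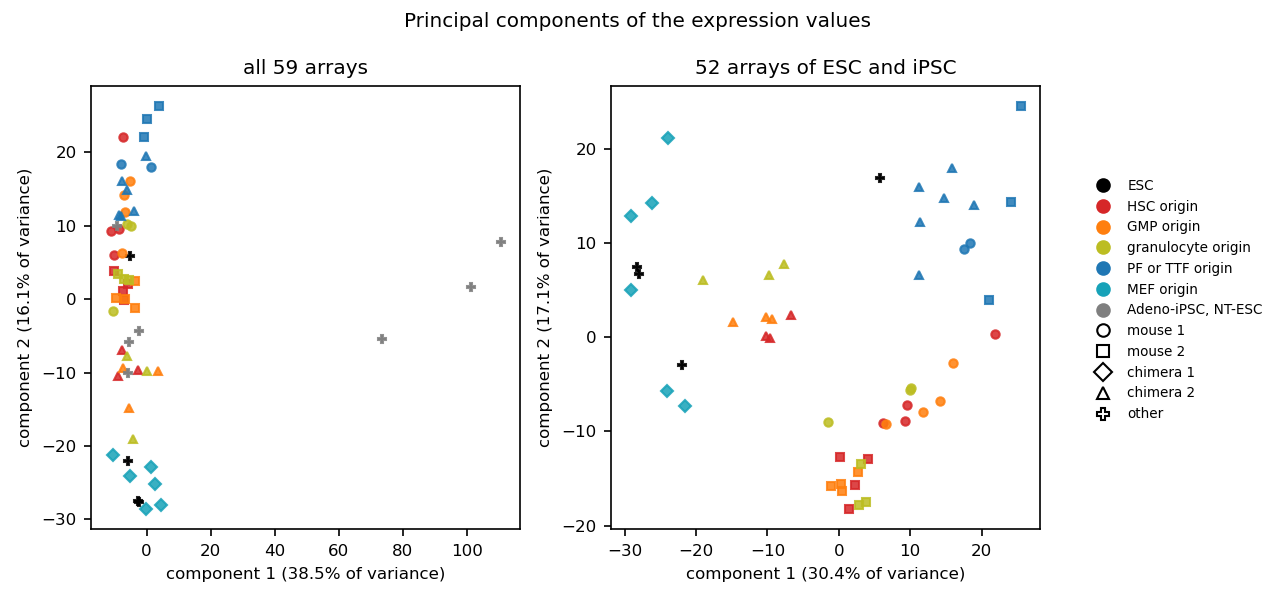
First against second principal component of the log2 values, each point 1 array coloured by class or origin, for all 59 arrays (left) and for the 52 ESC and iPSC arrays (right). NT-7, NT-8 and NT-9 lay apart from the other 56 arrays on the first component, and ESC-1 lay apart from the other 3 ESC clones.

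Among genes with a name, the largest differences between ESC and genetically matched iPSC from MEFs were in 2 maternally expressed noncoding transcripts of the Dlk1-Dio3 imprinted region. Rian was 1.17 ± 0.72 in iPSC (SD, n = 6) against 3.54 ± 0.11 in ESC (SD, n = 4), a log2 difference of -2.38 (SE 0.32). Meg3 was 0.65 ± 0.77 against 2.97 ± 0.29, a difference of -2.32 (SE 0.35). In all 6 iPSC clones every probe set of both transcripts, 4 for Meg3 and 3 for Rian, read below the lowest ESC. With 10 arrays and limma, neither passed an adjusted p under 0.05 over all 11807 genes (both 0.0669), and 0 genes did, although 997 had an unadjusted p under 0.05. Adjusted over the list alone, both maternal transcripts passed. This list was chosen with the series' own description at hand and is not independent evidence. The next smallest p-values, also not passing at 0.0669, were higher readings in iPSC of the germline transcription factor Dmrtb1 (0.69), Ggnbp2 (0.46) and the amidase gene Pm20d1 (0.63). Dlk1, a paternally expressed protein gene of the same region, differed by -0.22 (adjusted p = 0.868). The pluripotency factors did not pass either: Pou5f1 0.09, Sox2 -0.07, Nanog -0.08, Klf4 -0.06, Myc -0.28.

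Small shifts over whole gene groups were called, but only with camera's preset correlation, and random regroupings of the arrays gave as many lists in 66 of 100 splits. With camera's preset correlation, the 29 measured pluripotency genes lay lower in MEF-derived iPSC (median -0.15, adjusted p = 5.7e-05; adjusted p = 0.674 with an estimated correlation). Higher were the p53 targets (median 0.23, adjusted p = 5.7e-05; adjusted p = 0.655 with an estimated correlation) and germ cell genes (median 0.16, adjusted p = 2.9e-04; adjusted p = 0.655 with an estimated correlation). No member passed over all genes, while 6 germ cell genes and 4 p53 targets were higher when adjusted over the list alone. Over all 120 list tests of this study, 36 were called with the preset correlation and 0 with an estimated one, where the smallest adjusted p was 0.112. Leaving out 1 clone moved the gene count between 0 and 4: it was 4 without iPSC-6, Meg3 and Rian among them, 1 without iPSC-4 (Rian), and 2 without ESC-1. The mean of probe sets called 7 genes, and a single fit over all groups 203 (128 higher, 75 lower).

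Low Meg3 and Rian were found in iPSC of every origin. Of the 48 clones, 44 read below the lowest ESC in every probe set of both transcripts. The 4 others were fibroblast-derived and lay within 1 log2 unit of the ESC means: 1 of 2 PF clones of mouse 1 (iPSC-19) and 3 of 6 TTF clones of chimera 2 (iPSC-44, iPSC-47 and iPSC-49). Across the 3 animals that gave both blood and fibroblast clones, blood-derived clones were lower in Meg3 (0.65 ± 0.56, SD, n = 31, against 2.04 ± 1.03, SD, n = 11; difference -1.35, adjusted p = 2.0e-05) and in Rian (1.30 ± 0.70 against 2.64 ± 0.89; -1.37, adjusted p = 5.0e-05). Dlk1 was lower as well (-0.63, adjusted p = 1.6e-05). Adeno-2 read 0.27 for Meg3 and 1.26 for Rian.

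**Figure D2:**
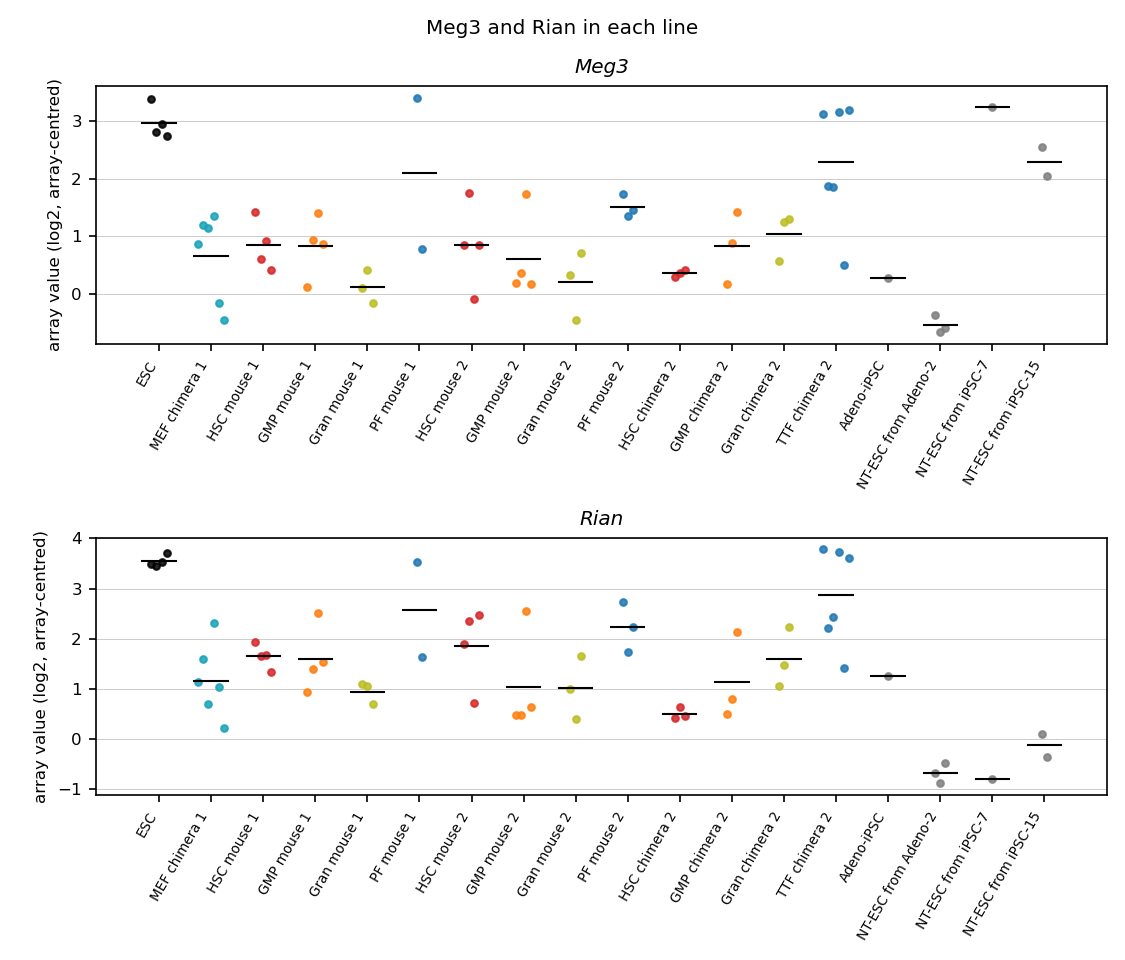
Log2 values of Meg3 and Rian, each point 1 line, grouped by class, cell of origin and animal, with a bar at the group mean. Most iPSC lay below ESC in both transcripts, 4 fibroblast-derived clones lay at the ESC level, and NT-ESC lay low in Rian but not all in Meg3.

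Against all 48 iPSC, 583 genes passed (298 higher and 285 lower in iPSC, 2663 with an unadjusted p under 0.05), 37 of them by 2-fold or more (8 higher, 29 lower). Among those higher were the transcription factors Wt1 (1.66, SE 0.40, adjusted p = 0.0123), Gbx2 (1.32), Etv1 (1.08) and Tcf15 (1.01), of which Gbx2 supports ESC self-renewal and Tcf15 marks ESC primed to leave it. The de novo DNA methyltransferase Dnmt3a was also higher (4.88 ± 0.48, SD, n = 48, against 3.79 ± 0.34, SD, n = 4; 1.10, SE 0.24, adjusted p = 0.00714), with the peptidase Dpp4 (1.29), neurofilament gene Nefh (1.15) and the guidance receptor Robo4 (1.04). Lower beside Meg3 (0.97 ± 0.92 against 2.97 ± 0.29, adjusted p = 0.00852) and Rian (-1.95, adjusted p = 0.0110) were the Notch ligand Dner (-1.79), trophoblast and blood regulator Gata2 (-1.47, SE 0.25, adjusted p = 5.9e-04), the keratin Krt7 (-1.33), the homeobox gene Hesx1 (-1.33) and the water channel Aqp3 (-1.29). Dppa3, which protects imprints in the early embryo, fell by 0.55, and Tfcp2l1 of the naive network fell by 0.53. Dlk1 (-0.16, adjusted p = 0.711), Pou5f1 (-0.23), Sox2 (-0.12), Nanog (-0.15), Klf4 (-0.31) and Myc (0.81, adjusted p = 0.144) did not pass.

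Serum-inducible immediate early genes were the group with most members lower: 7 of 14, such as Egr2 (-1.09), Fos (-0.77), Klf6 (-0.59) and Dusp1 (-0.57), and 10 when adjusted over the list alone (list adjusted p = 4.3e-09; adjusted p = 0.26 with an estimated correlation). Of 10 trophoblast genes 3 were lower, Gata2, Krt7 and Tfap2c (-0.43), and the same number when adjusted over the list alone (list adjusted p = 0.00228; adjusted p = 0.26 with an estimated correlation). Pluripotency genes had 2 of 29 lower, and 2 higher and 5 lower when adjusted over the list alone (list adjusted p = 0.0147; adjusted p = 0.674 with an estimated correlation). No cholesterol synthesis gene passed over all genes and 7 were lower when adjusted over the list alone (list adjusted p = 6.7e-04; adjusted p = 0.655 with an estimated correlation). With no member past the threshold in either adjustment, glycolysis and hypoxia genes (median -0.21, list adjusted p = 9.1e-04; adjusted p = 0.674 with an estimated correlation) and p53 targets (median -0.10, list adjusted p = 0.0221; adjusted p = 0.674 with an estimated correlation) lay lower. Fibroblast and feeder genes lay higher in iPSC (median 0.31, list adjusted p = 0.0217; adjusted p = 0.757 with an estimated correlation).

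These calls rested on few ESC clones and on how origins were weighed. Without ESC-1 the count was 1112, without ESC-2 6, without ESC-3 5 and without ESC-4 303. With the animal as a random block limma called 0 genes, with 900 at an unadjusted p under 0.05, and every gene named above lost its call there and without ESC-2 or ESC-3. MEF-derived clones read near ESC in many of these genes. Dnmt3a was 3.79 ± 0.34 in ESC (SD, n = 4) and 3.84 ± 0.55 in MEF-derived iPSC (SD, n = 6) but 4.73 to 5.27 in the other 12 origin groups. Fos was 5.46 in ESC and 5.42 in MEF-derived clones but 4.08 to 4.90 elsewhere, and Krt7 1.13 and 1.12 but -0.91 to 0.15. Without the MEF-derived clones the count was 2280 (1210 higher, 1070 lower).

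**Figure D3:**
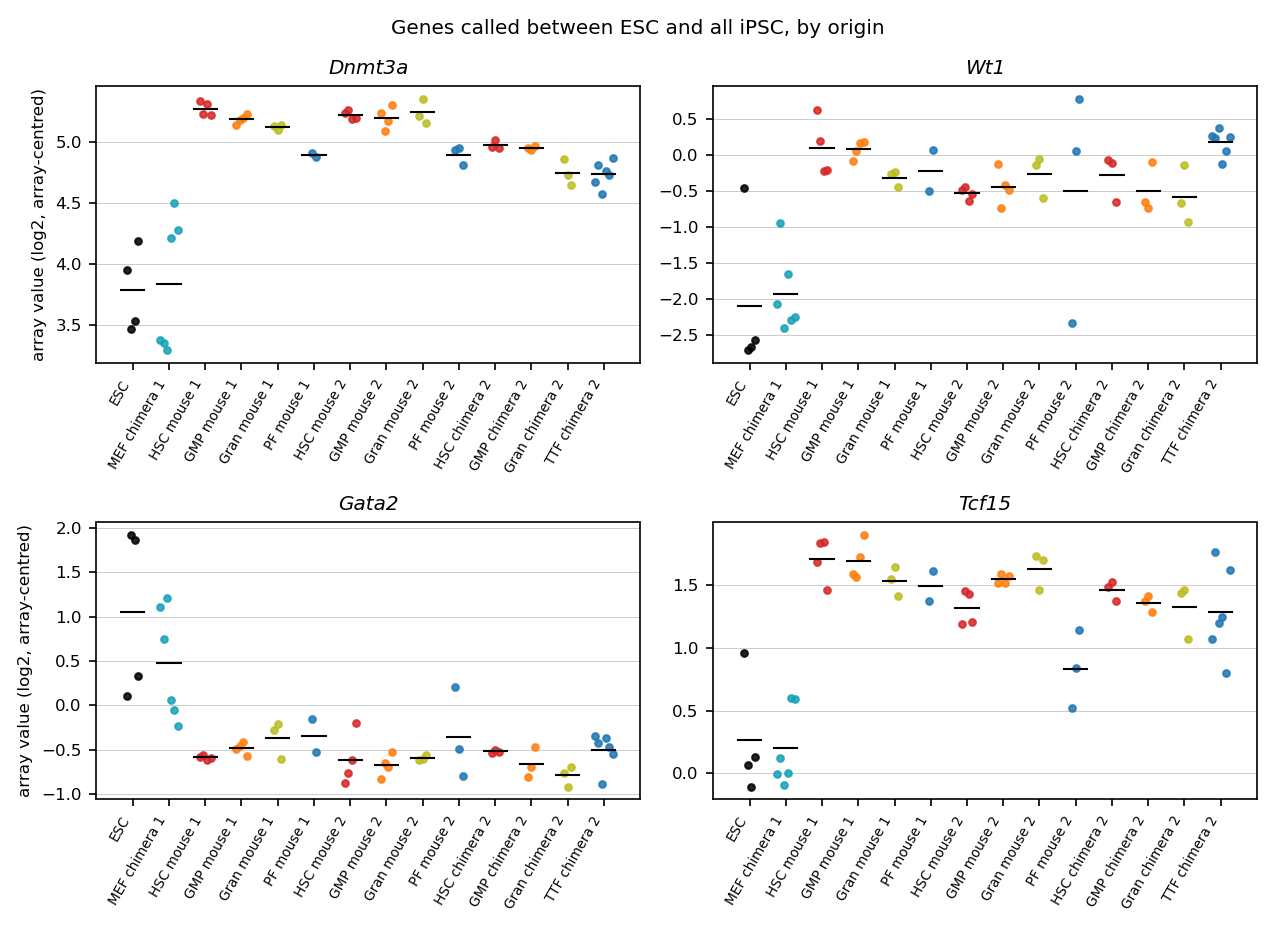
Log2 values of Dnmt3a, Wt1, Gata2 and Tcf15, each point 1 clone, grouped by ESC and by cell of origin and animal of the iPSC, with a bar at the group mean. MEF-derived clones read near ESC in Dnmt3a, Wt1 and Tcf15, and most other origins lay higher in these 3 and lower in Gata2.

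The 42 iPSC clones of 3 animals were compared by cell of origin. Any difference between HSC, GMP, granulocyte and fibroblast origin passed for 4488 genes, 118 with a range of 1 log2 unit or more, and for 2050 genes with 1 mean per animal and cell type. The widest ranges were in the imprinted retrogene Mcts2 (2.48, adjusted p = 4.4e-10), the scavenger receptor Olr1 (2.01), Sprr2a1 (1.96), Prl2c2 (1.95) and the semaphorin receptor Nrp1 (1.86). Sox2 (0.25, adjusted p = 0.0019) and Myc (0.54, adjusted p = 0.00433) also passed, and Pou5f1 (0.61, adjusted p = 0.149) and Nanog (0.07, adjusted p = 0.665) did not.

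Between blood-derived and fibroblast-derived clones 5870 genes passed (3320 higher and 2550 lower in blood-derived clones), 26 higher and 67 lower by 2-fold or more. Higher in blood-derived clones were Smc1b (0.50 ± 0.78, SD, n = 31, against -0.57 ± 0.56, SD, n = 11; 1.40, SE 0.14, adjusted p = 9.7e-11), Hormad1 (1.24), Stag3 (1.11) and Sycp3 (1.00), 4 genes with roles in meiosis. So were the AMP deaminase gene Ampd3 (1.33), the oxygen-sensing hydroxylase gene Egln3 (1.22) and Ndrg2 (1.11). Lower were Mcts2 (1.17 ± 0.89 against 3.80 ± 0.22; -2.36, SE 0.21, adjusted p = 1.7e-11), the matrix proteoglycan Dcn (-0.72 ± 0.51 against 0.96 ± 0.43; -1.63, adjusted p = 2.9e-11), the mesenchymal regulator Twist2 (-1.62), activin subunit gene Inhba (-1.57), chemokine gene Ccl7 (-1.59) and the adhesion receptor Alcam (-1.50). Of the reprogramming factors, Pou5f1 (0.59, adjusted p = 0.0223), Sox2 (0.24) and Klf4 (0.30) were higher and Myc (-0.49, adjusted p = 3.4e-04) lower, and Nanog (0.07, adjusted p = 0.221) did not pass. The size of the Pou5f1 difference came from 1 fibroblast-derived clone, iPSC-32, which read 0.28, and without it the difference was 0.17 (adjusted p = 3.7e-05). Pou5f1 and Myc lost their calls with 1 mean per animal and cell type, and Klf4 without mouse 2.

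Matrix and mesenchymal genes were almost uniformly lower in blood-derived clones: 25 of 28 fibroblast and feeder genes, such as Timp3 (-1.48), Prrx1 (-1.24) and Postn (-1.21), and 26 when adjusted over the list alone (list adjusted p = 4.8e-16; adjusted p = 0.403 with an estimated correlation). Their mean was 3.08 ± 0.19 in PF clones of mouse 2 (SD, n = 3) against 1.97 to 2.01 in its blood-derived groups, and 2.61 ± 0.23 in TTF clones of chimera 2 (SD, n = 6) against 1.78 to 1.90. In mouse 1 it differed little, with 2.63 in PF clones against 2.59 in HSC-derived, 2.49 in GMP-derived and 2.26 in granulocyte-derived clones, and it was 1.89 ± 0.43 in ESC (SD, n = 4). With this mean as a covariate, a fit chosen after the results were seen, 2252 genes passed in place of 5870, and Aldoc, Col4a1, Col4a2, Nr0b1, H2-D1, Pou5f1, Klf4 and Myc reversed direction, Aldoc to -0.26. Outside the list, 1284 of 3320 higher and 578 of 2525 lower genes kept their call. Median differences there went from 0.238 to 0.190 for the higher and from -0.224 to -0.162 for the lower genes. Without the covariate, glycolysis and hypoxia genes went the other way from the fibroblast list, 22 of 23 higher, as with Ndrg1 (1.05), Bnip3 (0.95) and Aldoc (0.83), and 22 when adjusted over the list alone (list adjusted p = 4.3e-09; adjusted p = 0.398 with an estimated correlation). Germ cell genes had 13 of 16 higher and 1 lower, with Tex11 (0.91) and the gonadal regulator Dmrt1 (0.87) among them, in the same numbers when adjusted over the list alone (list adjusted p = 6.3e-06; adjusted p = 0.285 with an estimated correlation). Mesoderm genes had 10 of 14 lower, including Mixl1 (-0.84) and Wnt3 (-0.73), and 11 when adjusted over the list alone (list adjusted p = 5.7e-04; adjusted p = 0.26 with an estimated correlation). Proliferation genes had 16 of 23 higher, including Aurkb (0.53), E2f1 (0.51) and Bub1 (0.50), and 2 lower, Ccnd2 (-0.79) being 1, with 17 and 2 when adjusted over the list alone (list adjusted p = 6.7e-04; adjusted p = 0.423 with an estimated correlation).

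Imprinted genes outside Dlk1-Dio3 had 9 of 32 higher and 12 lower, Magel2 (-0.87) among the latter, and pluripotency genes 15 of 29 higher, including Nr0b1 (0.41) and Fgf4 (0.39), and 3 lower. Amino acid and ER stress genes had 13 of 18 higher, including Trib3 (0.61) and Shmt2 (0.41), and 1 lower (list adjusted p = 0.0109; adjusted p = 0.674 with an estimated correlation). DNA methylation and Polycomb genes had 5 of 14 higher, including Ezh2 (0.38) and Dnmt3l (0.35), and 1 lower. Interferon-response and MHC genes had 1 of 18 higher and 6 lower, H2-D1 (-0.62) among them, haematopoietic genes 4 of 31 higher, including Coro1a (0.39), and 6 lower, including Cd53 (-1.53) and Lcp1 (-0.72). Cholesterol synthesis genes had 7 of 16 higher and 3 lower, p53 targets 4 of 17 higher and 5 lower, and epiblast genes 3 of 13 in each direction. Neuroectoderm genes had 2 of 11 in each direction, Neurod1 (1.02) being 1 of the higher, and 0 of 4 sex-linked genes passed. All these counts were the same when adjusted over the list alone. Immediate early genes had 2 of 14 higher and 7 lower (2 and 8 when adjusted over the list alone), trophoblast genes 2 of 10 higher and 5 lower, Krt8 (-0.84) among them (3 and 7), endoderm genes 3 of 18 higher and 5 lower, including Col4a2 (-0.84) and Col4a1 (-0.83) (2 and 4), and 2-cell-like genes 1 of 5 higher (0). Median, mean and test differed in sign for the 2-cell-like list (median -0.05, mean 0.09, test lower), neuroectoderm (median -0.07, mean 0.02, test lower) and sex-linked genes (median -0.03, mean 0.04, test lower).

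**Figure D4:**
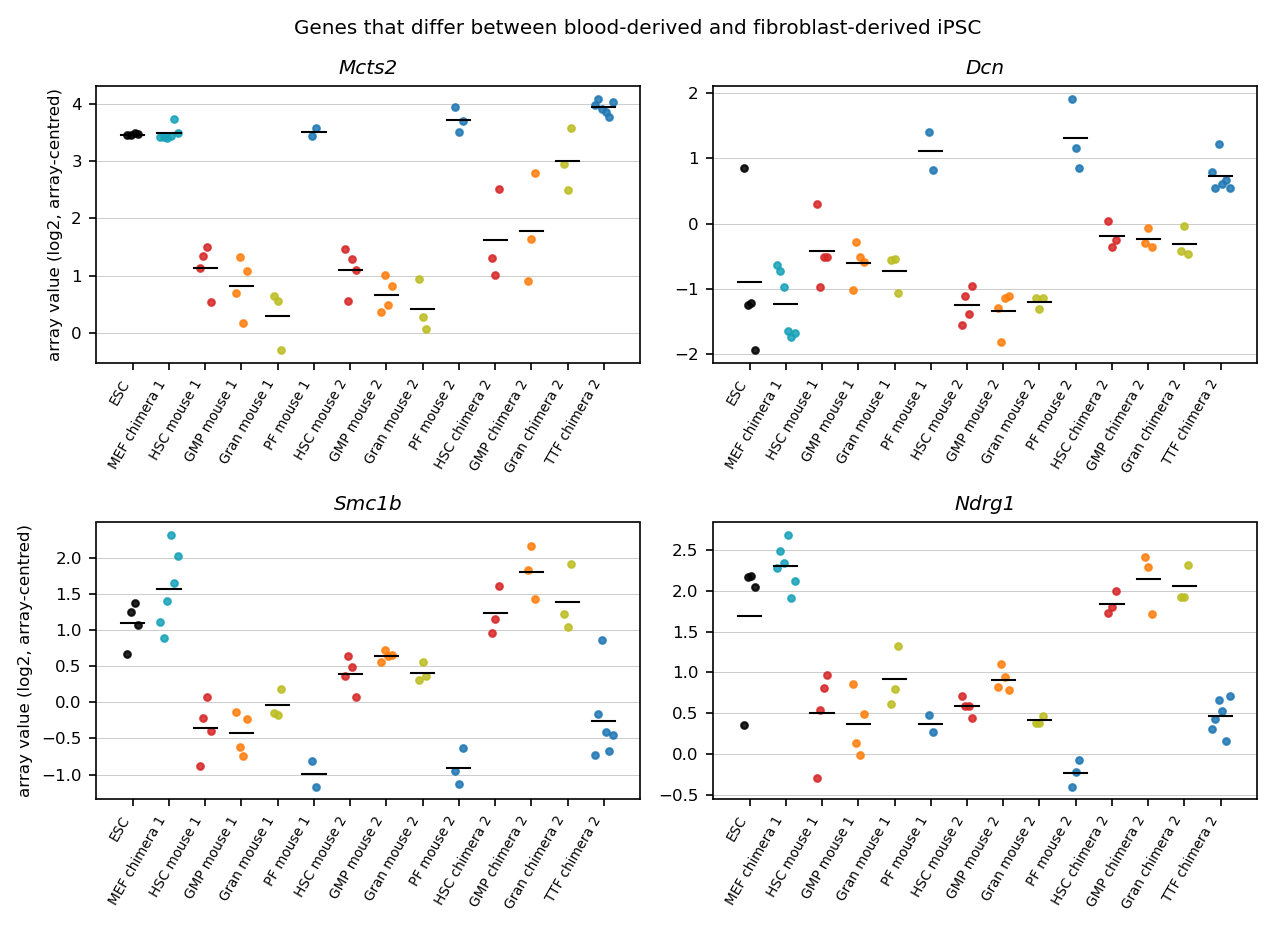
Log2 values of Mcts2, Dcn, Smc1b and Ndrg1, each point 1 clone, grouped by cell of origin and animal, with a bar at the group mean. Fibroblast-derived clones lay higher in Mcts2 and Dcn, and blood-derived clones higher in Smc1b and Ndrg1.

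HSC-derived and granulocyte-derived clones did not differ in any gene past the threshold: limma called 0 of 11807, with 390 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00. The smallest unadjusted p-values belonged to Pmel (-0.25, granulocyte minus HSC), Dgcr6 (0.18), Wnt5a (-0.53), the iron exporter Slc40a1 (0.55) and Jun (0.43), none passing. Meg3 (-0.27) and Rian (-0.22) did not pass. With 0.5 log2 units added to simulated genes, 89.6% were recovered by the same fit. Immediate early genes lay higher as a group in granulocyte-derived clones (median 0.14, adjusted p = 1.1e-08; adjusted p = 0.112 with an estimated correlation), with 0 of 14 over all genes and 3 when adjusted over the list alone. Trophoblast genes lay higher too (median 0.07, adjusted p = 0.0283; adjusted p = 0.26 with an estimated correlation). Lower were fibroblast and feeder genes (median -0.12, adjusted p = 1.1e-05; adjusted p = 0.674 with an estimated correlation), DNA methylation and Polycomb genes (median -0.03, adjusted p = 6.7e-04; adjusted p = 0.398 with an estimated correlation) and pluripotency genes (median -0.05, adjusted p = 0.00291; adjusted p = 0.674 with an estimated correlation). None of these 4 groups had a member past the threshold in either adjustment. The animals differed in these shifts: the fibroblast list mean was 2.59 in HSC-derived and 2.26 in granulocyte-derived clones of mouse 1 (iPSC-7 of the former 3.09), 1.97 and 2.00 in mouse 2, and 1.84 and 1.78 in chimera 2. The pluripotency list mean was 3.59 and 3.45 in chimera 2, 3.67 and 3.69 in mouse 1, and 3.72 and 3.71 in mouse 2.

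The animal of origin differed in 5307 genes, 112 with a range of 1 log2 unit or more. The noncoding transcript Gt(ROSA)26Sor, from the locus widely used for targeted insertions, had the widest range (4.18, adjusted p = 9.2e-23): its group means were -1.72 to -1.27 in mouse 2, 0.80 to 1.06 in mouse 1 and 1.75 to 3.21 in chimera 2, with 1.23 in ESC. Ctr9 of the elongation complex Paf1 (range 1.93, adjusted p = 5.7e-35) was 0.83 to 0.98 in mouse 1 against 2.57 to 3.01 in the other animals, and Trim12a (2.71) was lowest in mouse 1. Y-linked Eif2s3y (3.04, adjusted p = 4.1e-06) and Uty (2.15), the interferon-induced Oasl2 (1.86), Myb (1.81) and Bmp4 (1.77) also differed. Pluripotency genes passed in 16 of 29, with Nr5a2 (1.20), Fbxo15 (1.13), Myc (1.01) and Klf5 (0.88) among them, while Sox2 (0.08), Nanog (0.07), Klf4 (0.22), Meg3 (0.34), Rian (0.17) and Dlk1 (0.23) did not pass. Imprinted genes outside Dlk1-Dio3 passed in 17 of 32, such as Slc38a4 (0.99), Peg12 (0.90) and Peg3 (0.82). Without chimera 2 the count was 2033, and with 1 mean per animal and cell type 2764. The labels do not separate the animal from its reprogramming experiment or array batch.

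All 6 NT-ESC subclones read lower in Rian than ESC, and their donors Adeno-2, iPSC-7 and iPSC-15 already read below the lowest ESC. Rian was the only gene past the threshold between NT-ESC and ESC (-0.51 ± 0.36, SD, n = 6, against 3.54 ± 0.11, SD, n = 4; -4.05, SE 0.20, limma adjusted p = 5.1e-06; 2074 with an unadjusted p under 0.05). This fit did not account for subclones sharing a donor. With the donor line as a random block (correlation 0.832) Rian alone still passed in limma, with 98 genes at an unadjusted p under 0.05. Meg3 (-1.93, limma adjusted p = 0.275) did not pass: it was -0.54 ± 0.15 in the 3 subclones of Adeno-2 but 3.25 in NT-7 and 2.30 on average in NT-8 and NT-9. Pou5f1 (-0.44), Sox2 (-0.29), Nanog (-0.34), Klf4 (-0.09) and Myc (-0.24) did not pass. As groups, endoderm (median 0.92, adjusted p = 0.00768), haematopoietic (0.37, adjusted p = 0.00706), mesoderm (0.36, adjusted p = 0.0320) and 2-cell-like genes (1.01, adjusted p = 0.0037) lay higher. Proliferation (-0.52, adjusted p = 1.1e-05), cholesterol synthesis (-0.51, adjusted p = 5.1e-04), pluripotency (-0.16, adjusted p = 0.00135), glycolysis and hypoxia (-0.28, adjusted p = 0.00374) and p53 target genes (-0.32, adjusted p = 0.00505) lay lower. For p53 targets adjusted p = 0.26 with an estimated correlation, and for the other 8 groups it lay between 0.655 and 0.702. No member of these passed over all genes. When adjusted over the list alone, 4 of 5 2-cell-like genes were higher, 3 p53 targets and 1 cholesterol synthesis gene lower, and 1 endoderm gene passed in each direction. NT-7 on the one hand and NT-8 and NT-9 on the other averaged 1.14 and 1.80 for endoderm, 3.09 and 3.13 for pluripotency and 2.68 and 3.05 for proliferation genes. The subclones of Adeno-2 (-0.38, 3.71 and 3.87) lay close to ESC (-0.35, 3.70 and 3.88) in these. The values of NT-7, NT-8 and NT-9 were also less spread (array SD 2.35 to 2.47 against 2.54 to 2.64 in the other arrays). Whether this smaller spread moved the list values was not tested. Without NT-7, NT-8 and NT-9 the count was 468 (236 higher, 232 lower). Only subclones of Adeno-2 were then left, so this count compares 1 donor line with ESC and not NT-ESC in general.

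Against their own iPSC donors, 7 genes passed in NT-ESC. The protease inhibitor A2m (2.18, SE 0.23; 2.14 ± 0.46, SD, n = 6, against -0.16 ± 0.69, SD, n = 3; limma adjusted p = 0.0261) and the immediate early factor Fosb (1.36) were higher. The connexin Gjb2 (-2.06), Alcam (-2.03), the microfibril gene Mfap5 (-1.55), the heparan sulfate sulfotransferase Hs6st2 (-1.53) and the metalloprotease Mmp19 (-1.49) were lower. Rian (-1.89, limma adjusted p = 0.0600), Meg3 (0.93, limma adjusted p = 0.193), Dlk1 (-0.18) and Pou5f1 (-0.46, limma adjusted p = 0.0706) did not pass. The Meg3 estimate pooled opposite changes: it read 1.417 in iPSC-7 and 3.255 in NT-7, but was lower in the subclones of Adeno-2 than in Adeno-2. Immediate early genes were higher as a group, 1 over all genes and 11 when adjusted over the list alone (list adjusted p = 6.2e-04; adjusted p = 0.674 with an estimated correlation), and 10 proliferation genes were lower when adjusted over the list alone and 0 over all genes (list adjusted p = 1.7e-06; adjusted p = 0.674 with an estimated correlation). Haematopoietic genes (median 0.58, list adjusted p = 0.00371; adjusted p = 0.674 with an estimated correlation) and endoderm genes (median 0.87, list adjusted p = 0.0115; adjusted p = 0.702 with an estimated correlation) were also higher as groups. Lower were fibroblast and feeder genes (median -0.59, list adjusted p = 8.1e-04; adjusted p = 0.702 with an estimated correlation) and DNA methylation and Polycomb genes (median -0.57, list adjusted p = 5.1e-04; adjusted p = 0.674 with an estimated correlation). Over all genes 0 members of these 4 groups passed, and when adjusted over the list alone 13 haematopoietic genes were higher and 1 lower, 5 fibroblast and feeder genes lower, 4 DNA methylation and Polycomb genes lower and 0 endoderm genes past the threshold. The donor families were not alike in this. In the Adeno-2 family the endoderm mean was -0.38 in NT-ESC against -0.12 in the donor, and the haematopoietic mean -2.38 against -2.47, so both rises lay mainly in NT-7, NT-8 and NT-9. Whether the smaller spread of values in NT-7, NT-8 and NT-9 adds to these list shifts was not tested. The fibroblast list mean went from 2.74 in Adeno-2 to 1.40 in its subclones and from 3.09 in iPSC-7 to 2.38 in NT-7, but was 2.49 and 2.72 in NT-8 and NT-9 against 2.23 in their donor iPSC-15. Only 9 arrays entered, and 81.8% of simulated differences of 2 log2 units were recovered. The count was 0 without the donor block and without the family of iPSC-7, with 1158 and 2532 at an unadjusted p under 0.05 in limma. It was 12 without the family of iPSC-15 and 2434 without that of Adeno-2. Without NT-7, NT-8, NT-9 and their donors, Adeno-2 was the only donor array left. A count from that fit has no replicate on the donor side and describes 1 donor line only.

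Clones of one origin differed most in a short set of genes. The pooled within-origin SD had a median of 0.152 over all genes and passed 0.5 in 46. The 20 widest were led by Eif2s3y (1.32) and the keratinocyte envelope gene Sprr2a1 (0.96). Among them were the guanylate-binding genes Gbp2b (0.89), Gbp2 (0.85), Gbp3 (0.69) and Gbp7 (0.61), all on chromosome 3 of assembly GRCm38.p6, X-linked Xlr4b (0.88) and Rhox5 (0.65), Y-linked Uty (0.81) and Uba1y (0.69), and Rian (0.74) and Meg3 (0.74). Among ESC the guanylate-binding genes spread as widely (Gbp2b 0.96, Gbp2 0.86, Gbp3 0.86), while Rhox5 (0.06) and Rian (0.11) hardly varied. AF067061 (0.76), Usp17la (0.72), A2m (0.65), Car3 (0.64), Krt8 (0.61), Csn3 (0.60), Prl2c2 (0.59) and Ccnb1ip1 (0.59) completed the 20.

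In 3 of the 52 ESC and iPSC arrays, stretches of neighbouring genes shifted together relative to the other clones of the group. In iPSC-34 all of chromosome 11 read higher (median 0.35 over 534 genes, 90.4% of them above 0). In iPSC-2 the part from Myo19 to Tbcd did (0.34 over 229 genes, the rest of the chromosome -0.03) and in iPSC-46 the part from Tmem199 to Tbcd (0.35 over 255 genes). In iPSC-46 the part of chromosome 14 from Oxnad1 to Tmtc4 read lower (-0.69 over 160 genes, 96.3% of them below 0). The gene order was that of assembly GRCm38.p6, and no genomic measurement was analysed here.

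**Figure D5:**
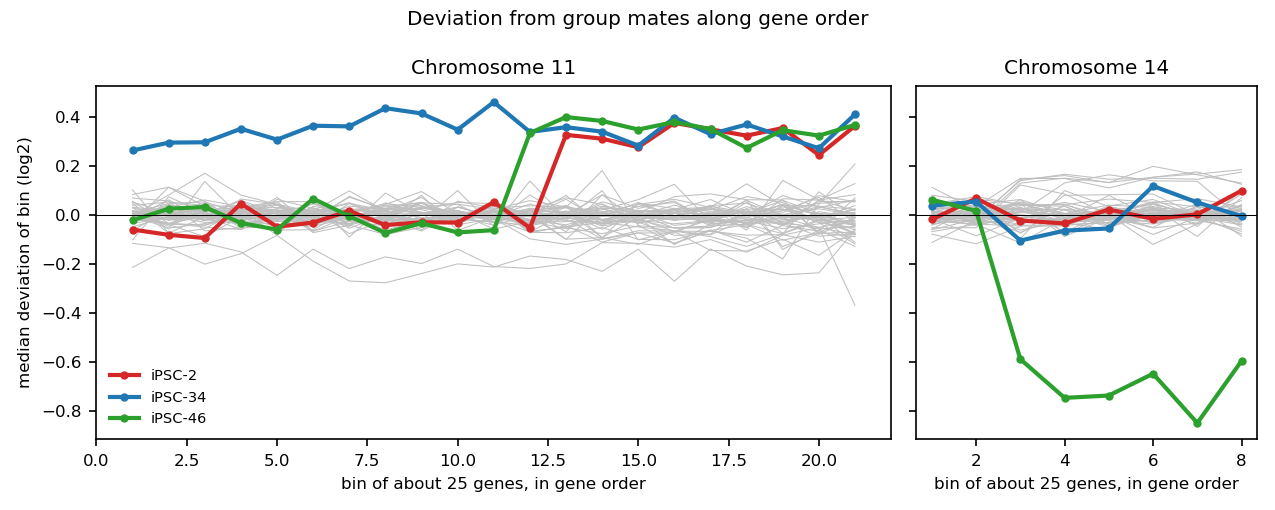
Median log2 deviation from the other clones of its group in consecutive bins of about 25 genes along chromosomes 11 and 14, each line 1 array. iPSC-2 (red), iPSC-34 (blue) and iPSC-46 (green) lay above the other arrays (grey) over all or part of chromosome 11, and iPSC-46 below them over most of chromosome 14.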

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

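The genes looked at here were picked after their comparisons had been seen, and the test of whether the blood and fibroblast contrast differs between animals was chosen only then. Of 150 groups of values tested, of named genes and of mean array correlations, 19 had 1 line apart from the rest by a Dixon-type rule, which picks about 1 group in 20 by chance, and all 19 were of named genes. ESC-1 carried 5 of these: Myc 1.96 against 0.62 to 0.66 in the other ESC, Wt1 -0.46 against -2.71 to -2.57, Zfp423 1.06, Hesx1 0.59 and Dppa3 3.13. In ESC-4 the peptidase Dpp4 was 2.35. The Dlk1-Dio3 transcripts stood apart in GMP-derived iPSC-27 of mouse 2, with Meg3 1.73 against 0.17 to 0.36 and Rian 2.55 against 0.48 to 0.64, as did Myc there (1.79). Y-linked transcripts were low in iPSC-14 (Eif2s3y -0.71 against 2.71 to 3.08, Uty -4.24) and high in iPSC-46 (Uty -0.33 against -4.32 to -2.98 in the other TTF clones, Uba1y 0.51 against -3.65 to -3.22). The others were Mcts2 in iPSC-5 (3.72), Myc in iPSC-11 (2.40) and iPSC-45 (2.67), Nanog (4.89) and Lefty1 (3.43) in iPSC-21, and Dlk1 in NT-9 (-0.21). None of these lines was left out of the main comparisons on this ground.

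The difference between blood-derived and fibroblast-derived clones itself differed between the 3 animals in 2445 genes (limma interaction terms, 4033 with an unadjusted p under 0.05). Of 99 permutations 0 gave as many, the highest being 1270. These permutations moved animal labels within each class and so also removed the difference between animals that both classes share. They therefore cannot decide on the interaction alone. Of 64 genes selected for the blood and fibroblast contrast, not all of them printed above, 41 were among the 2445. Most kept their direction with unequal size, and 27 genes overall had opposite directions by 0.5 log2 units or more. The contrast was widest in mouse 2 for Dcn (-2.58), Twist2 (-2.41), Prrx1 (-1.83), Postn (-1.75), Col4a2 (-1.41), Col4a1 (-1.24) and Sparc (-0.74). The same held for Prl2c2 (-2.41), Serpinb9b (-2.24), Inhba (-2.14), Cd53 (-2.11), Ccl7 (-2.07), H2-D1 (-1.54), Mixl1 (-1.18) and Lcp1 (-1.16), which were lower in blood-derived clones. Higher in them, and most so in mouse 2, were Neurod1 (1.74), Pou5f1 (1.69, against 0.18 in mouse 1 and 0.06 in chimera 2), Stag3 (1.62), Tnfsf13 (1.57), Tex11 (1.46), Bnip3 (1.29), Sycp3 (1.28), Nr0b1 (0.84), E2f1 (0.73), Shmt2 (0.59) and Fgf4 (0.57). The Pou5f1 value of mouse 2 was carried by iPSC-32, 1 of its 3 PF clones, which read 0.28, and without this clone the difference over all animals was 0.17 in place of 0.59.

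In chimera 2, whose fibroblast class is TTF, the contrast was widest for Ddx60 (2.41, against 0.16 in mouse 1 and 0.07 in mouse 2), A2m (2.11), Smc1b (1.74), Egln3 (1.57), Ndrg1 (1.55), Ndrg2 (1.37), Aldoc (1.09) and Aurkb (0.65). It was also widest there for Nrp1 (-2.18), Timp3 (-1.98), Alcam (-1.83), Ccnd2 (-1.09) and Myc (-0.79, against 0.33 in mouse 1). Mouse 1 had the widest contrast for Trib3 (1.29, against -0.01 in chimera 2) and Dnmt3l (0.77). All TTF clones came from chimera 2, so its differences from the mice do not tell animal from the labelled cell. Mouse 1 and mouse 2 both gave PF clones, and they differed as well, as in Alcam (-0.32 and -1.82), Timp3 (-0.13 and -1.66) and Twist2 (-0.77 and -2.41).

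Of 4623 probe sets without a single gene name, 2 passed between ESC and MEF-derived iPSC, 1 of them lower by a log2 difference of -2.50, 166 between ESC and all iPSC, 2062 between blood and fibroblast origin and 188 between NT-ESC and donors. None passed in limma between HSC and granulocyte origin or between NT-ESC and ESC, where 142 and 879 had an unadjusted p under 0.05. Of these probe sets 287 have several genes and 4336 none in the sources used here, and their values were not assigned to a gene.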

How the results depend on the processing

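The fits without NT-7, NT-8 and NT-9, without clones with shifted chromosome parts, without MEF-derived clones, and with the fibroblast list mean as a covariate were chosen after the results were seen. The cause of each shift was not tested. For ESC against MEF-iPSC the count of 0 became 6 probe sets when every probe set was tested, 7 genes with the mean of probe sets, 203 with 1 fit over all groups and 15 with the replicate number as a block. Clones of the same number correlated at r = 0.0625 to 0.354, 3 of 4 pairs over 0.1, and 2 of 4 ESC clones correlated best with their own number, so pairing by number was not established. Leaving out 1 clone gave 0 (for example ESC-2) to 4 (iPSC-6). For ESC against all iPSC, 583 became 3039 when each origin group had its own term and equal weight. Clones still entered singly there, and differences between origins left the error term. The count was 0 with the animal as a random block and 2280 without the MEF-derived clones, which are all of chimera 1. It was 72 without mouse 1, 211 without mouse 2 and 1051 without iPSC-2, iPSC-32, iPSC-34 and iPSC-46. Without ESC-3 it was 5 and without ESC-1 1112. Any difference between cells of origin fell from 4488 to 2050 genes with 1 mean per animal and cell type, and between animals from 5307 to 2764, or 2033 without chimera 2. Blood against fibroblast origin gave 2252 in place of 5870 with the fibroblast list mean as a covariate, where some genes reversed: Aldoc -0.26, Col4a1 0.022, Col4a2 0.22, Nr0b1 -0.060, H2-D1 0.10, Pou5f1 -0.16, Klf4 -0.14 and Myc 0.20. HSC against granulocyte origin stayed at 0 in all 53 alternatives. For NT-ESC against donor iPSC, 7 became 11 probe sets with every probe set, 12 with trend and robust settings, 5 (2 higher, 3 lower) with quantile normalization, 8371 with 1 fit over all groups and 0 without the donor block. It was 0 without the family of iPSC-7, 12 (0 higher, 12 lower) without that of iPSC-15, 2434 without that of Adeno-2 and 2042 without NT-7, NT-8 and NT-9, where Meg3 was -0.81. The fit without NT-7, NT-8 and NT-9 also left out their donors, so it compared sister subclones with 1 array, Adeno-2. With no replicate on the donor side, its count and Meg3 value describe 1 donor line and not NT-ESC against donors in general. For NT-ESC against ESC, 1 became 6 probe sets, 2 genes with the mean of probe sets, and 1 (without ESC-1) to 2 (without NT-7) on leaving out 1 line. It became 468 without NT-7, NT-8 and NT-9, which left only subclones of Adeno-2. Gene list calls went from 36 to 0 with an estimated correlation.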

Other observations

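Of the tests below, the random regroupings and the test of dimmer genes on shifted chromosome parts were written before their results, and all others were chosen only after the result was seen. Mcts2, an imprinted retrogene, had the widest range between origins. It read 3.46 ± 0.01 in ESC (SD, n = 4) and 3.50 to 3.94 in groups of fibroblast origin, but 0.30 to 1.13 in blood-derived groups of both mice. In chimera 2 it was 1.61 in HSC-derived, 1.78 in GMP-derived and 3.00 in granulocyte-derived clones. NT-7 read 1.84 with 1.13 in its donor iPSC-7, and NT-8 and NT-9 read 2.50 and 3.19 with 0.64 in their donor iPSC-15. The 3 subclones of Adeno-2 (3.85 on average) stayed near its 3.97.

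Y-linked Eif2s3y differed between clones of the same animal. In mouse 1, iPSC-14 (-0.71), iPSC-15 (-1.79) and iPSC-17 (-0.39) read low while other blood-derived clones read 2.33 to 3.50, and mouse 2 clones read 3.11 to 4.12. NT-7 read -2.40 although its donor iPSC-7 read 2.73. In iPSC-32, derived from a PF cell of mouse 2, Pou5f1 was 0.28 and Lefty1 0.01 while Nanog (5.17) and Sox2 (4.24) were at the level of other clones. Rhox5, an X-linked homeobox gene, ranged from -0.05 to 4.99 over the iPSC clones.

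Blood-derived and fibroblast-derived clones differed in 5870 genes. RNA of fibroblasts or feeder cells in the fibroblast-derived lines may add to the genes lower in blood-derived clones. Outside the fibroblast list, 22.9% of these stayed past the threshold with that list's mean as a covariate, a share that leaves this open. Their median difference went from -0.224 to -0.162, so calls were lost more than size. Such RNA is not enough for the 26 genes at least 1 log2 unit higher in blood-derived clones, because dilution lowers all pluripotent transcripts alike and the pluripotency genes had a median difference of only 0.156 (quartiles 0.0037 and 0.293). Unequal spread of the arrays is argued against by the 66.7% of calls that stayed with the array SD as a covariate. Altered states of the pluripotent cells themselves, such as the higher germ cell and glycolysis genes, were not separated from the culture of each clone.

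In genes called between ESC and iPSC of the other origins, MEF-derived clones lay near ESC. Over 2280 genes called without them, the ratio of the MEF-derived to the other difference had a median of -0.0044, and 87.4% of ratios were under 0.5, which argues against a change shared by every iPSC origin. Shared processing of ESC and MEF-derived arrays could give this too. ESC correlated by 0.0040 more with MEF-derived arrays (0.992) than with other iPSC (0.988). This leaves open whether processing, culture history, the genetic match named above, the animal or the cell of origin is the reason. No batch is given in the sources used here.

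Shifted chromosome parts in iPSC-2, iPSC-34 and iPSC-46 were longer than the longest run of 2 bins in shuffled gene order, which argues against chance clustering, and only 0.303% of bins elsewhere passed the same bound, which argues against poor quality of the whole array. Extra copies of chromosome 11 parts and missing copies on chromosome 14 are a candidate explanation. Of 582 dimmer genes on these parts that took no part in finding them, 67.4% deviated in the same direction (59.4% to 76.2% per part), between the bounds of 60% and 75% set beforehand, so this stays open.

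Random regroupings of the same arrays gave as many genes as the real one in 1 of 100 splits, the real one itself, for cells of origin (4488, highest other 1), for blood against fibroblast origin (5870, highest other 1867) and for animals (5307, highest other 2). A chance assignment of single clones was thus excluded for these at 0.05. The splits moved single clones, so they cannot exclude chance differences between whole animals or between derivations from them. For NT-ESC against donors (7, highest other 0) as many came up in 1 of 24 splits, the lowest share that 24 ways allow. The 7 calls became 0 without the donor block or without the family of iPSC-7, so this does not settle chance. For ESC against all iPSC as many came up in 3 of 100 splits, but the highest other split called 3517 against 583. For NT-ESC against ESC they did in 5 of 100, with 5247 against 1. Splits that call several times the real count point to a structure of the samples other than the tested one, and for NT-ESC against ESC chance was not excluded. For ESC against MEF-iPSC (0 genes, highest other 347) and HSC against granulocyte origin (0, highest other 0) all 100 of 100 gave as many. With a real count of 0 this was fixed in advance and says nothing about chance. For gene lists, adjusted here over the 20 lists of each comparison and not over all 120 tests, as many came up in 66 of 100 splits for ESC against MEF-iPSC (3 lists, highest other 12), 21 for ESC against all iPSC (7, highest other 11), 27 for blood against fibroblast origin (6, highest other 13), 16 for HSC against granulocyte origin (5, highest other 8), 26 for NT-ESC against ESC (9, highest other 12) and 7 of 24 for NT-ESC against donors (8, of which 6 passed over all 120 tests, highest other 9), so chance was not excluded for any list count.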
